A study of Mus musculus with 12 samples.

How the data were processed

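RNA sequencing measured gene expression in mouse peritoneal macrophages, cells recruited to the abdominal cavity by an injection of thioglycolate, an irritant broth. Per the labels' protocols, the cells were isolated on day 4 after the injection, plated, and stimulated the next day for 8 h with vehicle (BSA in PBS) or with 250 uM palmitate, a saturated fatty acid, together with 100 ng/ml LPS, the endotoxin of Gram-negative bacteria. The cells came from mice with the myeloid LysM-Cre driver alone (controls) or labelled as PPARγ knockouts made with the same driver. Total RNA was purified on Ambion columns and the libraries were made with the Clontech SMARTer v1 kit, per the labels' protocols. The 2 genotypes and 2 treatments gave 4 groups of 3 libraries, 12 in all, and each library was assigned to its group by its title.

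The submitters' processing notes name bcl2fastq 2.0, STAR 2.0.4b, Subread without a version, featureCounts 1.45 and the genome build GRCm38. The options, annotation release and strand setting are not given in the sources used here. Each library had 1 deposited table of 41388 Ensembl genes, with exon coordinates, exon length, the authors' raw count, CPM (the count scaled to the library's total) and RPKM (the same per kilobase of exon). The deposited counts were whole numbers. The deposited CPM equalled the count divided by the library's total count, and the deposited RPKM equalled that CPM divided by the exon length in kilobases, to rounding error. Of the gene IDs, 40254 were given a symbol from a table of gene names, and 1134 kept their ID. In GENCODE M21, an annotation of GRCm38, 40340 of the IDs were found, 40281 overlapped the gene of that ID on the same chromosome and 30702 had identical ends, so coordinates are printed as the deposited tables give them.

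All tests used the deposited counts. Genes with too few counts were removed with edgeR's filterByExpr by group, which left 12914 genes holding at least 99.92% of each library's counts. Libraries were scaled by TMM, and the quasi-likelihood F-test of edgeR 4.0.16 (robust dispersions, R 4.3.3) was fitted to all 12 libraries with 1 mean per group, so that the groups shared 1 estimate of the spread. There were 5 comparisons: genotype within each treatment, treatment within each genotype, and their interaction, which is the log2 response in the libraries labelled knockout minus that in the controls. P-values were adjusted over all genes of a comparison by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are given on the log2 scale ± standard error. Expression levels are TMM-normalised CPM as mean ± SD (n = 3) unless another unit is named. The gene-level values were computed from raw counts, and neither the deposited CPM nor the deposited RPKM entered a test.

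Before the data were examined, 31 gene lists and a rule for the genes named in the text were fixed. The rule took Pparg. It took Il1b, Il1a, Il18, Nlrp3, Casp1, Ifnb1, Tnf and Il6 whatever their p-value. In each comparison it took up to 6 genes with the highest and 6 with the lowest log2 fold change past the threshold, with at least 10 CPM in the higher group and no overlap between the groups' libraries (chance gives no overlap in 10% of comparisons of 3 against 3), without predicted genes, pseudogenes and antigen receptor segments. For the interaction, the 10 CPM applied to the highest group and the overlap rule was left out. For each list it took up to 4 members with the smallest p-value and up to 2 that went against the list's direction. Fewer were named than the rule allowed, and some results are left out because they are withheld for evaluation. The pathway lists were interferon-stimulated genes, type I interferon production and receptor signalling, interleukin-1 and inflammasome, LPS-responsive cytokines and NF-kB targets, PPAR targets, mitochondrial fatty acid oxidation, nuclear-encoded oxidative phosphorylation, glycolysis and hypoxia response, cholesterol synthesis and uptake, fatty acid synthesis, alternative activation, unfolded protein and integrated stress response, NRF2 oxidative stress response, lysosome and autophagy, MHC class II, MHC class I with the immunoproteasome, cell cycle, and scavenger, efferocytosis and complement receptors. Immediate early, mitochondrially encoded and ribosomal protein genes described RNA quality and handling. Marker lists covered large and small peritoneal macrophages, neutrophils, eosinophils, B cells, T and NK cells, mast cells, dendritic cells, fibroblasts with mesothelial cells, and erythroid cells. The 27 lists with at least 5 measured genes were tested with camera of limma 3.58.1, which asks whether a list moved relative to the other genes, with a preset inter-gene correlation of 0.01 and adjustment over 135 tests (27 lists in 5 comparisons). A count of members "adjusted over the list alone" applies the Benjamini-Hochberg method to the list's own members.

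Both kinds of test were run on simulated counts with the real library sizes and dispersions, and with each gene's mean share over all libraries in every group. For the comparison of genotypes in vehicle, with 12619 genes and 200 of them changed, 45.1% of the 1.5-fold, 77% of the 2-fold and 94.1% of the 4-fold changes were recovered, and 5.3% of the calls were false. For the interaction, with 12609 genes, the recovered shares were 17.9%, 78.1% and 88.4%, and 6.11% of the calls were false. A list shifted by 1.3-fold was called in all 5 comparisons, and 0 of the other lists were. The simulated genes varied independently, so the list test was checked only without real correlation between genes. Apart from the genes changed on purpose, the simulation held no treatment response, no shift in composition between groups and no outlying library. Its shares of false calls do not cover these.

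Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, its Wald test, limma-voom with quality weights, no low-count filter, a filter of 1 CPM in 3 libraries, fits of the 2 compared groups alone, blocks on the replicate number, glmTreat against a fold of 1.5, camera with an estimated correlation, fry, and leaving out each of the 12 libraries in turn. Scaling by total count, and list members without vehicle replicate 1 labelled knockout, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.

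Library totals lay between 17960457 and 22696385 counts, so 3 counts corresponded to between 0.132 and 0.167 CPM. Reads carried no molecular identifiers, so intervals and floors cover counting error only. Nothing in the labels says that replicates came from separate animals or cultures, and the p-values measure the spread between these samples, which may be technical. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom from 2.44 to 47), so each library was counted as 1 replicate.

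The way the counts were made limits some genes. Genes with near-identical copies may be undercounted, as Gapdh appears to be, at 10.3 CPM in control vehicle libraries. Values of close paralogs (H2-Q6 and H2-Q7, the Ifit, Gbp and Ms4a families, ribosomal protein genes) are uncertain. Because the strand setting is not given, reads of overlapping genes could not be told apart. Among named genes this concerns Il1a (11.2% of its exon length shared with another gene), Il27 (10.1%), Irf5 (14.2%), Sqstm1 (17.3%), Cxcl16 (18.3%), Tap2 (18.5%) and Htr2b (11.8%). The counts are per gene and do not resolve the exons removed by a conditional allele.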

Results

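Macrophages from mice labelled PPARγ knockout and from Cre controls were compared with and without 8 h of palmitate plus LPS. PPARγ, encoded by Pparg, is a nuclear receptor that is activated by fatty acids and drives genes of lipid uptake and storage. The series asks how its loss alters the release of interleukin-1β and interleukin-1α, and names a dependence on type I interferon. The 12 libraries, 3 per group, held 17960457 to 22696385 counts each. Treatment separated the libraries along the first principal component, which held 86.2% of the variance. On the second component, with 3.96% of the variance, vehicle replicate 1 labelled knockout stood at 31.8, while replicates 2 and 3 of its group stood at -6.9 and -10. Ribosomal protein genes held 1.04% of the counts of that library, against 0.751% and 0.765% in the other 2.

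The targeted gene went against its label. Pparg (ENSMUSG00000000440, GRCm38 chromosome 6, 115361221 to 115490401, plus strand) had 73.5, 71.3 and 67.2 CPM per library total in the control vehicle libraries. The vehicle libraries labelled knockout had 115, 104 and 112 CPM. After TMM scaling the means were 61.6 ± 0.687 and 99.4 ± 10.6 CPM, a log2 difference of 0.69 ± 0.11 (edgeR quasi-likelihood adjusted p = 0.00124). With palmitate plus LPS the control libraries had 3.41, 2.55 and 3.75 CPM and those labelled knockout 3.04, 4.36 and 4.11 CPM, a log2 difference of 0.33 ± 0.16 that did not pass the threshold (edgeR adjusted p = 0.177). The groups are therefore called libraries labelled knockout, and each direction between genotypes below rests on labels that the gene-level Pparg count does not bear out. Counts per gene include exons outside the deleted part of a conditional allele, so they do not check the deletion itself.

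**Figure D1:**
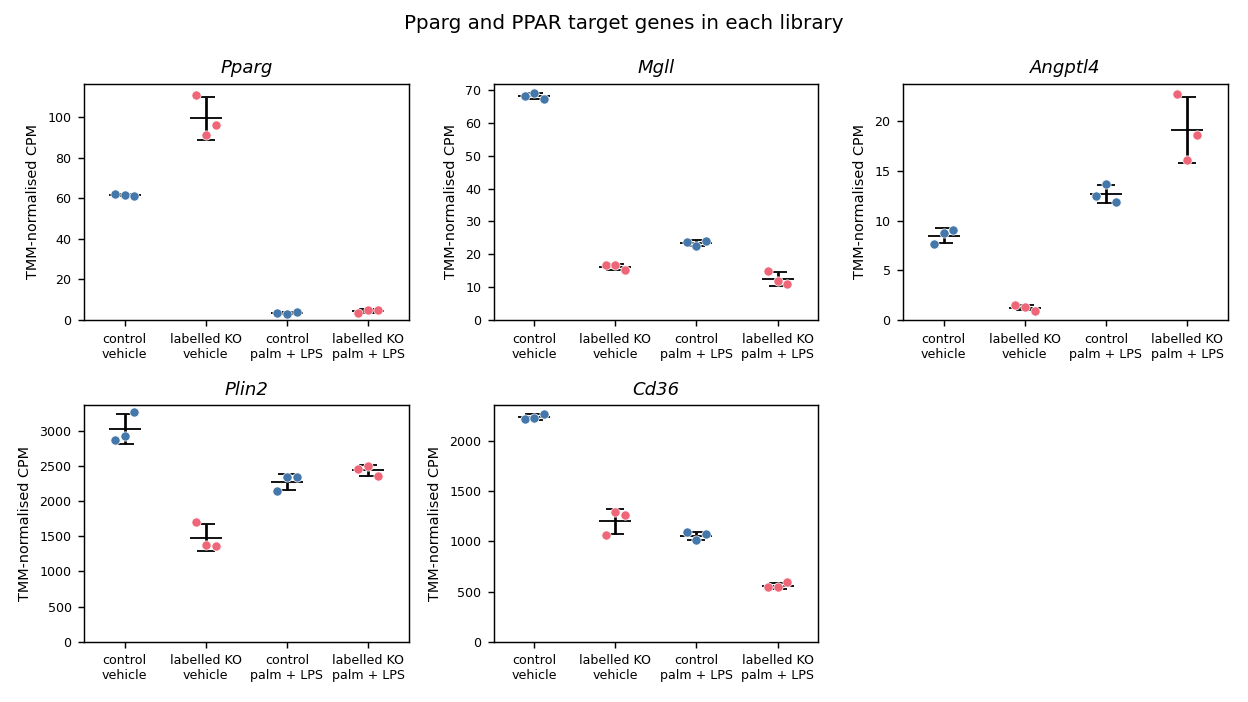
TMM-normalised CPM of Pparg and 4 PPAR target genes in each of the 12 libraries, by group; points are libraries, horizontal marks are means and bars are SD (n = 3). Pparg counts were higher in vehicle libraries labelled knockout (99.4 against 61.6 CPM), while Mgll, Angptl4, Plin2 and Cd36 were lower there.

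The first comparison asks how the genotypes differed without stimulation. PPAR target genes were lower in the vehicle libraries labelled knockout. Mgll, a lipase that splits monoglycerides, stood at 16.3 ± 0.917 CPM against 68.2 ± 0.855 in controls, a log2 difference of -2.07 ± 0.1 (edgeR adjusted p = 1.99e-08). Angptl4, an inhibitor of lipoprotein lipase, differed by -2.78 ± 0.18, the lipid droplet protein gene Plin2 by -1.03 ± 0.09 and the fatty acid receptor gene Cd36 by -0.9 ± 0.08. Of 59 interferon-stimulated genes 10 were higher, and the call of that list was lost with an estimated correlation (camera adjusted p = 0.112). Il1b and Il1a did not differ past the threshold. In 3 of 20 other settings Il1a passed it as lower, with log2 differences from -0.29 to -0.13 over the 20.

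Of 32 measured PPAR target genes, 11 were lower, 0 higher and 21 not called. Adjusted over the list alone, 13 were lower and 1 higher. The list median was -0.22 (camera adjusted p = 4.48e-25), and its call was the only one of this comparison kept with an estimated correlation (adjusted p = 0.00131). Mitochondrial fatty acid oxidation had 4 of 20 members lower and 16 not called (5 lower when adjusted over the list alone; camera adjusted p = 0.00128, adjusted p = 0.494 with an estimated correlation). These were Hadhb (-0.87 ± 0.1), Cpt1a, the carnitine transferase that admits long-chain fatty acids to mitochondria (-0.68 ± 0.12), Hadha (-0.47 ± 0.07) and Acadl (-0.46 ± 0.07).

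Among 59 measured interferon-stimulated genes, 10 were higher, 0 lower and 49 not called, and 21 were higher when adjusted over the list alone. The median was 0.24 (camera adjusted p = 1.54e-08, adjusted p = 0.112 with an estimated correlation). Examples are Rtp4 (0.54 ± 0.11), Usp18, which restrains interferon receptor signalling (0.52 ± 0.1), Rsad2 (0.48 ± 0.09) and Gbp3 (0.47 ± 0.09). All 4 lost their call when only the 2 groups were fitted (edgeR adjusted p up to 0.122), as did Cpt1a (adjusted p = 0.0807), and Rtp4 and Usp18 also without control replicate 1 or 2. MHC class I genes had 0 of 19 members called over all genes and 9 higher when adjusted over the list alone (median 0.27, camera adjusted p = 3.98e-05, adjusted p = 0.342 with an estimated correlation). For MHC class II the counts were 0 of 9 and 6 (median 0.41, camera adjusted p = 0.000209, adjusted p = 0.408 with an estimated correlation). LPS-responsive genes had 2 of 49 higher, 0 lower and 47 not called, with 6 higher when adjusted over the list alone (median 0.15, camera adjusted p = 0.00143, adjusted p = 0.349 with an estimated correlation). One of them was Cxcl16, a chemokine that also acts as a scavenger receptor (0.84 ± 0.08).

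In the interleukin-1 and inflammasome list, 3 of 22 members were higher, 1 lower and 18 not called (3 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.591). Higher were Il18bp, encoding a protein that binds interleukin-18 (0.92 ± 0.13), and Il1rn, encoding the interleukin-1 receptor antagonist (0.47 ± 0.09), whose call was lost with the 2 groups alone (edgeR adjusted p = 0.0706). Nlrc4, an inflammasome sensor, was lower (-0.86 ± 0.15). Il1b differed by 0.22 ± 0.14 (edgeR adjusted p = 0.472), Il1a by -0.19 ± 0.09 (adjusted p = 0.329), Il18 by 0.22 ± 0.15 (adjusted p = 0.489), Tnf by 0.21 ± 0.08 (adjusted p = 0.211) and Il6 by 0.22 ± 0.2 (adjusted p = 0.602). Nlrp3 (0.02 ± 0.21, adjusted p = 0.979) and Casp1 (0.08 ± 0.11, adjusted p = 0.75) were near 0. Ifnb1 had 0, 1 and 0 counts in the control libraries and 0 in each library labelled knockout, too few for a fold.

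Of scavenger, efferocytosis and complement receptor genes, 7 of 29 were higher, 4 lower and 18 not called (10 and 4 when adjusted over the list alone; camera adjusted p = 0.0174, adjusted p = 0.494 with an estimated correlation). C1qa and C1qc, subunits of the complement protein C1q, were both higher by 0.79 (SE 0.08 and 0.09). The apoptotic-cell receptor gene Axl was lower by -0.84 ± 0.12. Neutrophil markers had 2 of 7 higher, 1 lower and 4 not called (2 and 1 when adjusted over the list alone; camera adjusted p = 0.0332, adjusted p = 0.494 with an estimated correlation), with Mmp8 at 1.42 ± 0.13 and Mmp9 at -0.83 ± 0.16. Summed neutrophil marker CPM was 121 ± 1.53 against 91.3 ± 1.25, with Mmp8 at 43.7 against 16.4 and Csf3r at 63 against 57.2. S100a8 stood at 5.24 against 4.99 CPM, and S100a9 and Ly6g at 0 CPM in the libraries labelled knockout. Fibroblast and mesothelial markers summed to 178 ± 22 CPM against 134 ± 11.5, with 0 of 12 called and 1 higher when adjusted over the list alone (camera adjusted p = 0.048, adjusted p = 0.729 with an estimated correlation and 0.0879 without replicate 1 labelled knockout). The largest differences above 10 CPM included Ms4a4a (1.8 ± 0.2), Mmp8, Folr2 (1.28 ± 0.13), Htr2b (1.18 ± 0.1), Aif1 (1.18 ± 0.2) and Tgfbi (1.17 ± 0.12) on the higher side. On the lower side they included Cmbl (-2.35 ± 0.22), Mt3 (-2.31 ± 0.17), Sort1 (-2.21 ± 0.13) and Mgll. Arg1, the arginase of alternatively activated macrophages, was lower by -1.03 ± 0.13 and Stab1, of the same list, higher by 0.73. Of 21 alternative activation genes, 3 were higher, 2 lower and 16 not called (4 and 3 when adjusted over the list alone, camera adjusted p = 0.916).

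In all, 491 of 12914 genes passed the edgeR threshold in vehicle, 273 higher and 218 lower in the libraries labelled knockout. The count was 789 without vehicle replicate 1 labelled knockout, and 261, 263 and 322 without control vehicle replicates 1, 2 and 3. Ribosomal protein genes moved with that library: their median was 0.22 (camera adjusted p = 0.00616, adjusted p = 0.9 with an estimated correlation; 0 of 30 higher, 1 lower, 29 not called, and 1 lower when adjusted over the list alone) and -0.01 without it. Without it, 7 of 20 fatty acid oxidation genes were lower, 3 of 19 MHC class I genes higher, and 6 of 8 mitochondrially encoded genes lower (camera adjusted p = 1.09e-05, adjusted p = 0.513 with an estimated correlation), against 0 of 8 with it (camera adjusted p = 0.368).

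The second comparison asks how the genotypes differed after palmitate plus LPS. Interferon-stimulated genes were higher and Il1b was lower in the libraries labelled knockout. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139, minus strand), the precursor of interleukin-1β, stood at 2150 ± 242 CPM against 4160 ± 573 in controls, a log2 difference of -0.96 ± 0.11 (edgeR adjusted p = 4.03e-05). Il1a (ENSMUSG00000027399, chromosome 2, 129299610 to 129309972, minus strand) stood at 5860 ± 326 against 7650 ± 308 CPM, a difference of -0.38 ± 0.09 (edgeR adjusted p = 0.00665). Tnf (0.13 ± 0.07, adjusted p = 0.264), Il6 (0.12 ± 0.1, adjusted p = 0.457), Il18 (0.14 ± 0.13, adjusted p = 0.508) and Casp1 (0 ± 0.11, adjusted p = 0.983) did not pass the edgeR threshold.

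**Figure D2:**
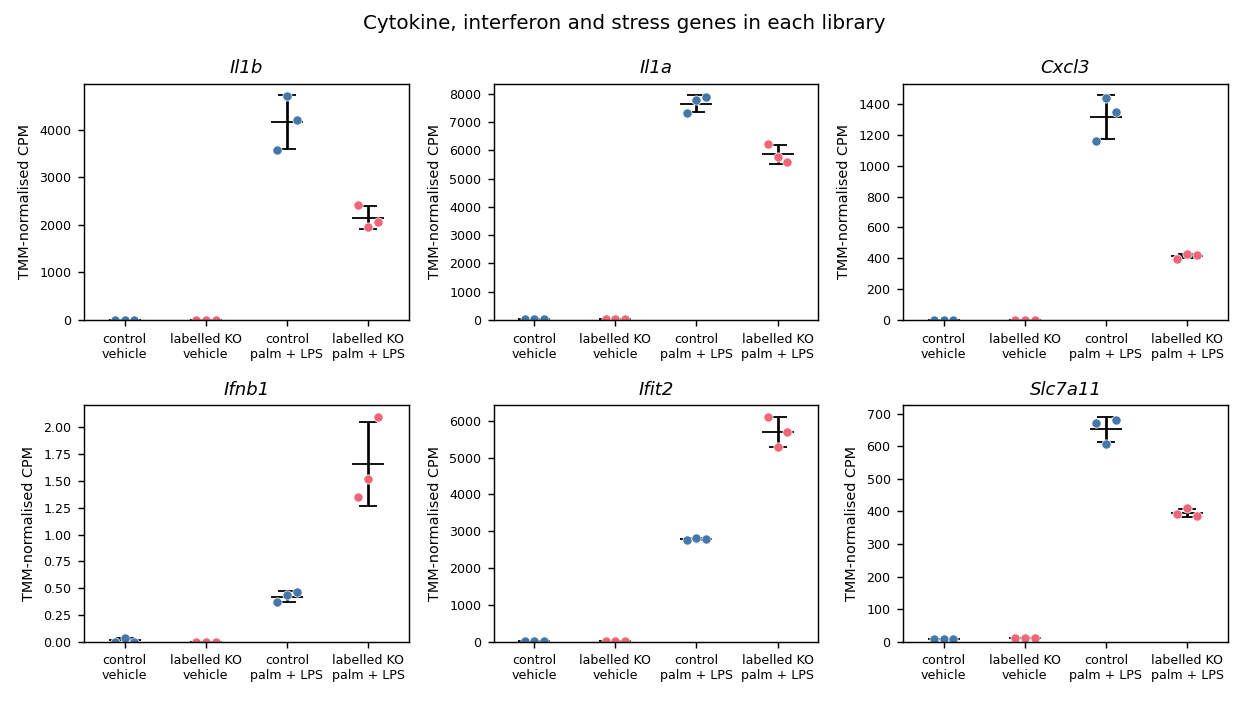
TMM-normalised CPM of Il1b, Il1a, Cxcl3, Ifnb1, Ifit2 and Slc7a11 in each of the 12 libraries, by group; points are libraries, horizontal marks are means and bars are SD (n = 3). After palmitate plus LPS, Il1b, Il1a, Cxcl3 and Slc7a11 were lower and Ifnb1 and Ifit2 higher in the 3 libraries labelled knockout than in the 3 controls.

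Ifnb1 (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774, minus strand), which encodes interferon-β, had 23, 28 and 40 counts in the stimulated libraries labelled knockout and 7, 8 and 9 in the controls. The log2 difference was 1.96 ± 0.33 (edgeR adjusted p = 0.00121), and the ratio of the summed counts was 3.96 with an exact 95% counting interval of 2.5 to 6.49. Of 59 interferon-stimulated genes, 50 were higher, 0 lower and 9 not called, with 52 higher when adjusted over the list alone. The median was 0.56 (camera adjusted p = 6.43e-43, adjusted p = 0.0013 with an estimated correlation), the only list of this comparison called both ways. Ifit2, which inhibits viral translation, rose from 2790 ± 18.8 to 5690 ± 413 CPM between the control libraries and those labelled knockout, a difference of 1.03 ± 0.07. Ifi44 differed by 1.04 ± 0.08 and the antiviral GTPase gene Mx1 by 0.98 ± 0.08.

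Interferon production and receptor signalling genes had 8 of 22 higher, 1 lower and 13 not called (9 and 2 when adjusted over the list alone; median 0.22, camera adjusted p = 0.00343, adjusted p = 0.494 with an estimated correlation). The RNA sensor gene Tlr3 was higher by 1.42 ± 0.17, Irf5 by 0.62 ± 0.07 and the kinase gene Ikbke by 0.43 ± 0.09, and Socs3, an inhibitor of cytokine receptor signalling, was lower by -0.5 ± 0.11. MHC class I and immunoproteasome genes had 12 of 19 higher, 0 lower and 7 not called (14 higher when adjusted over the list alone; median 0.34, camera adjusted p = 1.35e-09, adjusted p = 0.122 with an estimated correlation). Examples are H2-Q6 (1.15 ± 0.08), H2-Q7 (0.85 ± 0.1), the transactivator gene Nlrc5 (0.72 ± 0.11) and the peptide transporter gene Tap2 (0.51 ± 0.07).

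In the interleukin-1 and inflammasome list, 8 of 22 members were higher, 3 lower and 11 not called (9 and 3 when adjusted over the list alone; median 0.26, camera adjusted p = 0.00745, adjusted p = 0.349 with an estimated correlation). The higher members included 2 genes of secreted inhibitors, Il18bp (1.47 ± 0.1) and Il1rn (0.93 ± 0.09, from 1310 ± 75 to 2500 ± 93.6 CPM), and Mefv, which encodes pyrin (1.11 ± 0.15). Nlrp3, the sensor of the inflammasome that matures interleukin-1β, was higher by 0.58 ± 0.17 (edgeR adjusted p = 0.0266). Among other settings, it missed the threshold with total-count scaling (edgeR adjusted p = 0.106), without control replicate 2 or 3, and without any 1 of the 3 stimulated libraries labelled knockout (adjusted p up to 0.124). LPS-responsive cytokine genes went both ways: 13 of 49 were higher, 7 lower and 29 not called (14 and 9 when adjusted over the list alone; median 0.12, camera adjusted p = 0.328). Il27 was higher by 1.26 ± 0.08 and Nos2, the inducible nitric oxide synthase, by 1.1 ± 0.09. Lower were the neutrophil attractant Cxcl3 (-1.66 ± 0.09, from 1320 ± 143 to 415 ± 16.1 CPM) and Il23a (-1.23 ± 0.15).

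PPAR targets had 9 of 32 lower, 3 higher and 20 not called (10 and 3 when adjusted over the list alone; median -0.05, mean -0.15, camera adjusted p = 0.00251, adjusted p = 0.273 with an estimated correlation). Olr1, a receptor of oxidised lipoprotein (-0.96 ± 0.11), Cd36 (-0.91 ± 0.08), Mgll (-0.91 ± 0.11) and Lpl (-0.53 ± 0.08) were lower. Angptl4 (0.59 ± 0.14, edgeR adjusted p = 0.00795) and Cpt1a (0.47 ± 0.12, edgeR adjusted p = 0.0132) were higher. The call of Angptl4 was lost without replicate 1 labelled knockout (adjusted p = 0.0544), and that of Cpt1a without control replicate 1 or 2 or replicate 3 labelled knockout, and with total-count scaling (adjusted p = 0.0762). Fatty acid oxidation genes had 7 of 20 lower, 1 higher and 12 not called (10 and 1 when adjusted over the list alone; median -0.27, camera adjusted p = 0.00302, adjusted p = 0.514 with an estimated correlation), with Eci1 at -0.65 ± 0.11 and Echs1 at -0.53 ± 0.1.

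Cholesterol synthesis genes had 15 of 25 lower, 0 higher and 10 not called (17 lower when adjusted over the list alone; median -0.37, camera adjusted p = 4.87e-07, adjusted p = 0.203 with an estimated correlation), among them Pmvk (-0.81 ± 0.14), Mvd (-0.6 ± 0.08), Acat2 (-0.54 ± 0.09) and Nsdhl (-0.54 ± 0.1). Of NRF2 response genes, which counter oxidative stress, 9 of 21 were lower, 0 higher and 12 not called (13 lower when adjusted over the list alone; median -0.33, camera adjusted p = 6.32e-08, adjusted p = 0.202 with an estimated correlation). Cbr3 was lower by -0.99 ± 0.15, the cystine transporter gene Slc7a11 by -0.72 ± 0.07, Mgst1 by -0.59 ± 0.12 and catalase (Cat) by -0.43 ± 0.08. Fatty acid synthesis had 2 of 17 lower and 15 not called (2 lower when adjusted over the list alone; camera adjusted p = 0.0449, adjusted p = 0.659 with an estimated correlation), and oxidative phosphorylation 0 of 30 called (0 when adjusted over the list alone; median -0.15, camera adjusted p = 0.0174, adjusted p = 0.892 with an estimated correlation). Without vehicle replicate 1 labelled knockout, 14 of the 30 oxidative phosphorylation genes and 16 of 21 NRF2 genes were lower, with 0 higher in either list. Fatty acid oxidation then had 11 of 20 lower and 1 higher, and fatty acid synthesis 4 of 17 lower and 1 higher. LPS-responsive genes still went both ways in that fit, with 17 of 49 higher and 11 lower.

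Some markers of other cells also differed after stimulation. Fibroblast and mesothelial markers summed to 252 ± 76.9 CPM in the libraries labelled knockout (336 in replicate 1) against 133 ± 10.4 in controls. Of their 12 measured members, 6 were higher and 6 not called (7 higher when adjusted over the list alone; median 0.81, camera adjusted p = 0.000216, adjusted p = 0.355 with an estimated correlation), including the collagen genes Col1a1 (1.43 ± 0.25), Col1a2 (1.29 ± 0.18) and Col3a1 (1.19 ± 0.29) and Pdgfra (1 ± 0.21). Col3a1 lost its call without control replicate 2 or without replicate 1 labelled knockout (edgeR adjusted p up to 0.0583). Summed neutrophil markers were 170 ± 19.5 against 129 ± 6.43 CPM, with Mmp8 (1.18 ± 0.16) and Csf3r (0.59 ± 0.09) among the 2 of 7 members that were higher, 1 lower and 4 not called (2 and 1 when adjusted over the list alone). The list was not called (camera adjusted p = 0.916), and Csf3r alone held 136 of the 170 CPM.

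The largest differences after stimulation included Adra1a (2.2 ± 0.13), Gbp4 (1.98 ± 0.11), Dio2 (1.97 ± 0.16), St3gal5 (1.83 ± 0.18), Thbs1 (1.79 ± 0.23) and Klrk1 (1.76 ± 0.14) on the higher side. On the lower side they included Tmem154 (-1.84 ± 0.09), Cdkn1c (-1.67 ± 0.15), Cxcl3, Rab3il1 (-1.63 ± 0.18) and Il1f9 (-1.45 ± 0.14), a member of the interleukin-1 family. In all, 2081 genes passed the edgeR threshold, 1293 higher and 788 lower. Scaling by total count gave 2419 genes, 841 higher and 1578 lower, so the balance of directions depends on the scaling. The count was 4080 without vehicle replicate 1 labelled knockout. That library is in neither stimulated group and enters this comparison only through the spread shared by all groups, the filter and the scaling. The count was 1269 and 1227 without control replicates 2 and 3, and 1268 and 1333 without replicates 1 and 3 labelled knockout.

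**Figure D3:**
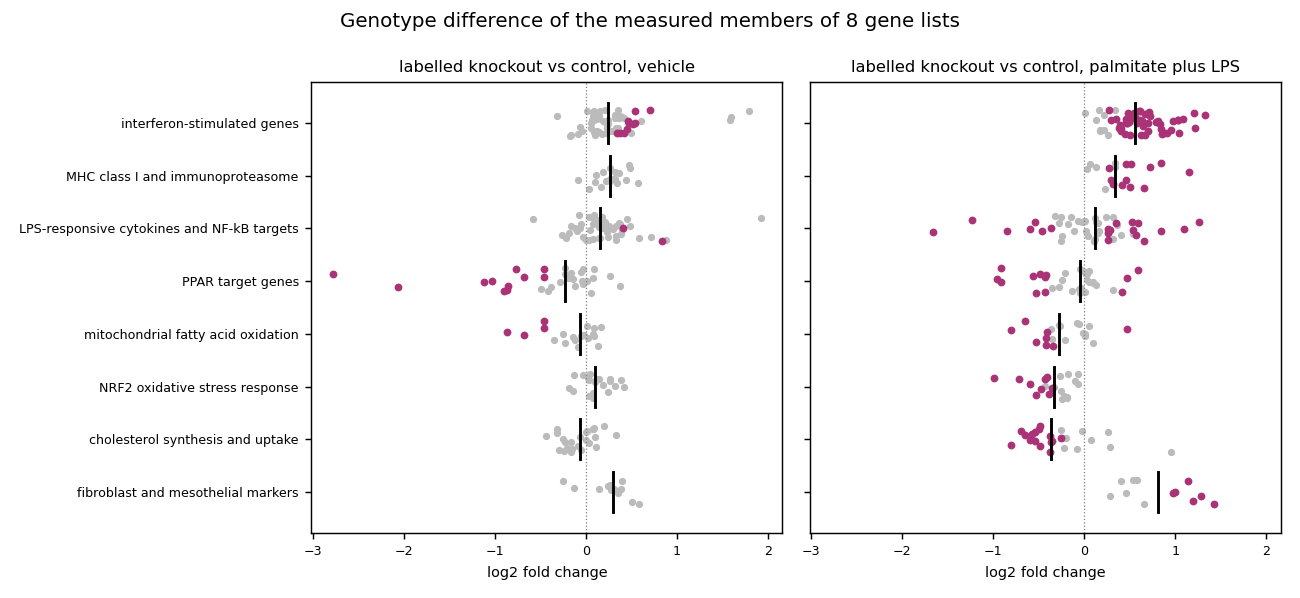
Log2 fold change between libraries labelled knockout and controls for each measured member of 8 gene lists, in vehicle (left) and after palmitate plus LPS (right); coloured points passed the edgeR threshold, grey points did not, and black bars are list medians. The median of interferon-stimulated genes was 0.24 in vehicle and 0.56 after stimulation, and that of NRF2 response genes 0.1 and -0.33; with total-count scaling the interferon median after stimulation was 0.47.

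Palmitate plus LPS altered most of the transcriptome of control macrophages. Cytokine genes rose: Il1b by 9.18 ± 0.17 on the log2 scale, from 7.16 ± 0.367 to 4160 ± 573 CPM, and Il1a by 7.6 ± 0.12. Il6 rose by 8.93 ± 0.15, Tnf by 6.96 ± 0.1, Nlrp3 by 3.67 ± 0.19, Il18 by 3.54 ± 0.15 and Casp1 by 2.25 ± 0.11. Pparg fell by -4.11 ± 0.14 (edgeR adjusted p = 3.22e-13). Ifnb1 had 24 summed counts against 1, a ratio of 30.7 with an exact 95% counting interval of 5.01 to 1260.

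All 59 interferon-stimulated genes rose in controls (59 when adjusted over the list alone; median 4.92, camera adjusted p = 5.11e-152, adjusted p = 0.00013 with an estimated correlation), such as Ifit1 (8.23 ± 0.11), Ifit2 (8.12 ± 0.1) and Mx1 (7.92 ± 0.12). LPS-responsive genes had 48 of 49 higher and 1 lower (48 and 1 when adjusted over the list alone; median 5.3, camera adjusted p = 1.16e-91, adjusted p = 0.00013 with an estimated correlation), with Cxcl3 at 9.38 ± 0.14, Edn1 at 8.58 ± 0.13, the chemokine gene Ccl5 at 8.56 ± 0.12 and Il27 at 7.77 ± 0.11. MHC class I had 19 of 19 higher (19 when adjusted over the list alone; median 2.62, camera adjusted p = 4.58e-19, adjusted p = 0.0454 with an estimated correlation), including Tap1 (4.69 ± 0.12) and Tap2 (2.86 ± 0.08). Interleukin-1 and inflammasome genes had 14 of 22 higher, 6 lower and 2 not called (14 and 6 when adjusted over the list alone; camera adjusted p = 1.8e-07, adjusted p = 0.0621 with an estimated correlation).

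The stress response list had 19 of 26 higher, 2 lower and 5 not called (19 and 2 when adjusted over the list alone; median 1.2, camera adjusted p = 3.16e-05, adjusted p = 0.683 with an estimated correlation), with Chac1 (3.87 ± 0.19), Asns (2.89 ± 0.12) and Ppp1r15a (2.83 ± 0.13). NRF2 genes had 14 of 21 higher, 4 lower and 3 not called (14 and 4 when adjusted over the list alone; camera adjusted p = 0.000293, adjusted p = 0.494 with an estimated correlation), led by Slc7a11 (6.14 ± 0.09) and Sqstm1 (2.91 ± 0.1). Interferon production and signalling had 14 of 22 higher, 2 lower and 6 not called (14 and 2 when adjusted over the list alone; camera adjusted p = 0.002, adjusted p = 0.471 with an estimated correlation). Lysosomal genes had 23 of 35 lower, 4 higher and 8 not called (24 and 4 when adjusted over the list alone; camera adjusted p = 0.00669, adjusted p = 0.499 with an estimated correlation), with the acid lipase gene Lipa at -1.67 ± 0.07 and Psap at -1.27 ± 0.09. Fatty acid oxidation had 16 of 20 lower, 2 higher and 2 not called (16 and 2 when adjusted over the list alone; camera adjusted p = 0.0335, adjusted p = 0.729 with an estimated correlation), with Hadh (-2.14 ± 0.1), Acaa2 (-1.78 ± 0.12) and Ech1 (-1.43 ± 0.12) lower and Acadl (0.61 ± 0.07) and Etfa (0.59 ± 0.09) higher. Tarm1 (8.8 ± 0.16) was among the genes with the largest rise. Cd28 (-5.57 ± 0.12), St6gal1 (-5.56 ± 0.2), Rasgrp3 (-5.48 ± 0.26) and Arhgap19 (-5.38 ± 0.23) were among those with the largest fall. In all, 8612 genes passed the edgeR threshold, 4132 higher and 4480 lower. Scaling by total count shifted the median of all genes by -0.332 and gave 2644 higher and 6416 lower.

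The libraries labelled knockout responded along the same lines. Il1b rose by 8.01 ± 0.16, Il1a by 7.4 ± 0.11, Il6 by 8.83 ± 0.15, Tnf by 6.88 ± 0.1, Nlrp3 by 4.24 ± 0.2, Il18 by 3.45 ± 0.15 and Casp1 by 2.17 ± 0.11. Pparg fell by -4.47 ± 0.14 (edgeR adjusted p = 8.29e-14). Ifnb1 had 91 summed counts after stimulation and 0 in vehicle, at least 38.1-fold higher against a floor of 3 counts over the group. Across 12914 genes, the log2 responses of the 2 genotypes had a Pearson r of 0.938; genes are not independent replicates.

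All 59 interferon-stimulated genes also rose here (59 when adjusted over the list alone; median 5.27, camera adjusted p = 1.43e-151, adjusted p = 0.00013 with an estimated correlation), with Ifit2 at 8.78 ± 0.1, Ifit1 at 8.45 ± 0.11, Mx1 at 8.43 ± 0.12 and Cmpk2 at 8.13 ± 0.12. LPS-responsive genes had 48 of 49 higher and 1 not called (48 when adjusted over the list alone; camera adjusted p = 9.93e-80, adjusted p = 0.000168 with an estimated correlation). MHC class I had 19 of 19 higher (19 when adjusted over the list alone; camera adjusted p = 2.86e-19, adjusted p = 0.0454 with an estimated correlation), including Tap1 (5.04 ± 0.12) and Tap2 (3.33 ± 0.08). Interleukin-1 and inflammasome genes had 16 of 22 higher, 4 lower and 2 not called (16 and 4 when adjusted over the list alone; camera adjusted p = 2.14e-08, adjusted p = 0.0458 with an estimated correlation). Without vehicle replicate 1 labelled knockout, the estimated-correlation calls of MHC class I in both genotypes (camera adjusted p = 0.11 in controls and 0.0839 here) and of the interleukin-1 list (0.116) were lost. Cholesterol synthesis genes had 15 of 25 lower, 3 higher and 7 not called (15 and 3 when adjusted over the list alone; camera adjusted p = 0.0479, adjusted p = 0.771 with an estimated correlation), with Dhcr7 (-3.04 ± 0.11), Mvk (-1.35 ± 0.11) and Sc5d (-0.75 ± 0.08) lower.

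Stress response genes had 19 of 26 higher, 3 lower and 4 not called (22 and 3 when adjusted over the list alone; camera adjusted p = 0.000402, adjusted p = 0.771 with an estimated correlation), with Asns at 3 ± 0.12. Interferon production and signalling had 17 of 22 higher, 1 lower and 4 not called (17 and 1 when adjusted over the list alone; camera adjusted p = 0.000137, adjusted p = 0.279 with an estimated correlation). Lysosomal genes had 23 of 35 lower, 4 higher and 8 not called (23 and 4 when adjusted over the list alone; camera adjusted p = 0.0149, adjusted p = 0.534 with an estimated correlation), with Lipa at -1.67 ± 0.07 and Ctsd at -1.4 ± 0.09. Fatty acid oxidation had 15 of 20 lower, 3 higher and 2 not called (15 and 3 when adjusted over the list alone; camera adjusted p = 0.0335, adjusted p = 0.729 with an estimated correlation), with Hadh at -2.68 ± 0.11 and Acaa2 at -1.98 ± 0.12. The largest rises included Ifi208 (9.43 ± 0.21), the interleukin-12 subunit gene Il12b (9.17 ± 0.18), Nos2 (9.04 ± 0.14) and Ptgs2, which makes prostaglandins (8.81 ± 0.14). Cd28 (-6.05 ± 0.13), St6gal1 (-5.81 ± 0.21), Rasgrp3 (-5.43 ± 0.27), Gpr183 (-5.31 ± 0.22), Thbd (-5.05 ± 0.19) and Galnt9 (-4.95 ± 0.16) were among the genes with large falls. The threshold was passed by 8956 genes, 4356 higher and 4600 lower (edgeR). Scaling by total count shifted the median of all genes by -0.369 and gave 2676 higher and 6570 lower.

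**Figure D4:**
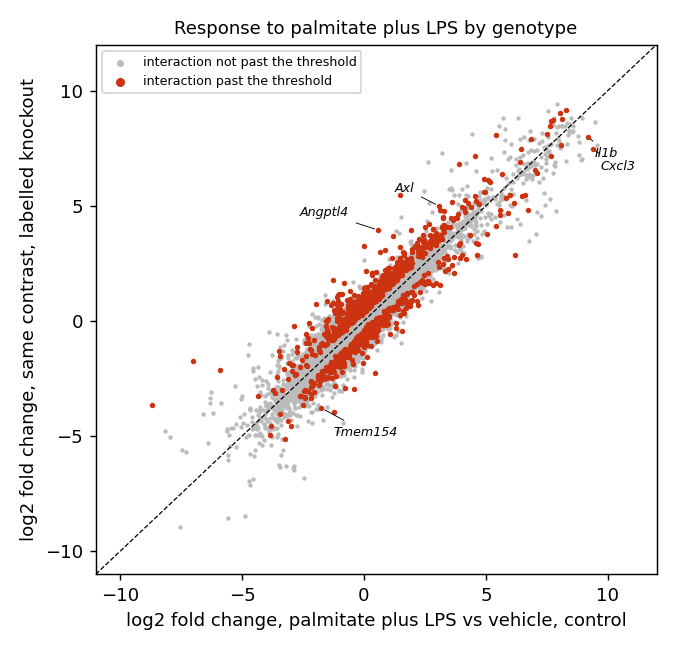
Fitted log2 fold change after palmitate plus LPS in controls (horizontal axis) and in libraries labelled knockout (vertical axis) for 12914 genes; red points passed the edgeR threshold for the interaction, and the dashed line marks equal responses. The responses lay along the line (Pearson r 0.938 across genes), with Il1b, Cxcl3 and Tmem154 below it and Angptl4 and Axl above it; fitted values of genes with few counts are uncertain.

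The interaction tests whether the response itself differed between the genotypes as labelled. Il1b rose less in the libraries labelled knockout, by a log2 difference of -1.17 ± 0.18 (edgeR adjusted p = 0.00175), and Cxcl3 by -1.91 ± 0.19 (edgeR adjusted p = 4.31e-05). The response of Il1a (-0.2 ± 0.13, adjusted p = 0.323), Tnf (-0.08 ± 0.11, adjusted p = 0.663), Il6 (-0.1 ± 0.22, adjusted p = 0.8), Il18 (-0.09 ± 0.2, adjusted p = 0.814), Casp1 (-0.07 ± 0.16, adjusted p = 0.787), Nlrp3 (0.56 ± 0.26, adjusted p = 0.185) and Pparg (-0.36 ± 0.19, adjusted p = 0.249) did not pass the edgeR threshold for a difference. Nor did that of Ifnb1 (edgeR adjusted p = 0.245), whose vehicle counts were too few for a fold. Angptl4, at 1.25 ± 0.287 CPM in vehicle libraries labelled knockout and 19.1 ± 3.34 after stimulation, had an interaction of 3.37 ± 0.23, against 8.5 ± 0.741 and 12.7 ± 0.938 CPM in controls.

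Interferon-stimulated genes had a larger rise for 15 of 59 members, a smaller one for 1 and 43 not called (25 and 1 when adjusted over the list alone; median 0.31, camera adjusted p = 8.68e-08, adjusted p = 0.125 with an estimated correlation). Without vehicle replicate 1 labelled knockout the larger rise was called for 24 and the smaller one for 1. Examples are Samd9l (1.26 ± 0.22), Slfn8 (0.79 ± 0.16), the RNA sensor gene Ifih1 (0.7 ± 0.14) and Ifit2 (0.65 ± 0.11), and Rtp4 went the other way (-0.53 ± 0.15). The call of Rtp4 was lost in 8 of the 12 fits without 1 library (edgeR adjusted p up to 0.109). Interferon production and signalling had 4 of 22 positive, 1 negative and 17 not called (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0174, adjusted p = 0.608 with an estimated correlation), with Tlr3 at 1.54 ± 0.27, Ikbke at 0.61 ± 0.13, Irf5 at 0.43 ± 0.1 and Socs3 at -0.8 ± 0.2. Irf5 lost its call in 5 fits without 1 library (edgeR adjusted p up to 0.0816) and Socs3 in 3 (adjusted p up to 0.06). NRF2 genes had 8 of 21 with a negative interaction, 0 positive and 13 not called (14 negative when adjusted over the list alone; median -0.44, camera adjusted p = 4.36e-09, adjusted p = 0.15 with an estimated correlation), with Cbr3 (-1.04 ± 0.2), Slc7a11 (-1.03 ± 0.11), the glutathione synthesis gene Gclm (-0.92 ± 0.17) and Srxn1 (-0.62 ± 0.12). Cholesterol synthesis had 8 of 25 negative and 17 not called (10 negative when adjusted over the list alone; camera adjusted p = 0.00251, adjusted p = 0.499 with an estimated correlation), including Pmvk (-0.84 ± 0.19) and Nsdhl (-0.65 ± 0.14). Pmvk lost its call in 4 fits without 1 library (edgeR adjusted p up to 0.0568).

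PPAR targets had 9 of 32 with a positive interaction, 3 negative and 20 not called (12 and 5 when adjusted over the list alone; median 0.19, camera adjusted p = 0.000191, adjusted p = 0.15 with an estimated correlation). Without vehicle replicate 1 labelled knockout, 12 were positive and 6 negative (camera adjusted p = 3.72e-08, adjusted p = 0.0992 with an estimated correlation). With all libraries, Mgll (1.16 ± 0.14), Plin2 (1.13 ± 0.13) and the oxysterol receptor gene Nr1h3 (1.13 ± 0.16) were positive and Olr1 (-1.22 ± 0.24) and Lpl (-0.55 ± 0.11) negative. Mgll and Plin2 had lower vehicle levels in the libraries labelled knockout, and Plin2 stood at 2440 ± 78.4 CPM there after stimulation against 2270 ± 118 in controls. Ribosomal protein genes had 1 of 30 positive, 2 negative and 27 not called (1 and 2 when adjusted over the list alone; median -0.39, camera adjusted p = 7.63e-05, adjusted p = 0.875 with an estimated correlation), and a median of -0.18 with 5 negative without vehicle replicate 1 labelled knockout. For oxidative phosphorylation 0 of 30 were called (0 when adjusted over the list alone; median -0.27, and -0.11 without that library; camera adjusted p = 0.00257, adjusted p = 0.875 with an estimated correlation), and for fibroblast and mesothelial markers 0 of 12 (0 when adjusted over the list alone; median 0.68, camera adjusted p = 0.0305, adjusted p = 0.7 with an estimated correlation and 0.107 without that library). Axl (1.93 ± 0.16), Adra1a (1.83 ± 0.16), Tmem154 (-2.03 ± 0.12), Batf3 (-2 ± 0.2), Gpr84 (-1.89 ± 0.23) and P2rx7, an ATP-gated channel upstream of the NLRP3 inflammasome (0.99 ± 0.17), also differed. The interleukin-1 and inflammasome list, which holds P2rx7, had 3 of 22 positive, 1 negative and 18 not called (4 and 1 when adjusted over the list alone, camera adjusted p = 0.152). Without vehicle replicate 1 labelled knockout, 6 were positive and 1 negative (camera adjusted p = 0.0366, adjusted p = 0.723 with an estimated correlation).

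In all, 1039 genes passed the edgeR threshold for the interaction, 607 positive and 432 negative. Among them, 310 rose in controls and rose further in the libraries labelled knockout, and 169 rose in controls and rose less or fell there. Scaling by total count gave 1176 genes, 388 positive and 788 negative. Leaving out 1 library gave between 428 and 1962 genes, with 1752 without vehicle replicate 1 labelled knockout. Across genes, the genotype differences in vehicle and after stimulation had a Pearson r of 0.122 (jackknife SE 0.13, 0.056 to 0.211 without 1 library) and a Spearman correlation of -0.02. Of the genes called in both, 111 were higher in both (27.3 if the calls were independent), 49 lower in both (13.3 if independent) and 41 opposite.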

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

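Tests of partial exposure, RNA of other cells, swapped labels, hidden deleted exons, scaling and stimulus strength were chosen only after the result was seen; those of exon length, fibroblast RNA and other splits were chosen before. The genes and lists of the next paragraph were picked out by the edgeR interaction term or the camera test of it. Pparg and vehicle replicate 1 labelled knockout, treated after them, were picked out because they go against their label or their group.

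The interaction, on the log2 scale, was positive for Angptl4 (3.37), Axl (1.93), Adra1a (1.83), Tlr3 (1.54), Samd9l (1.26), Mgll (1.16), Plin2 (1.13), Nr1h3 (1.13), P2rx7 (0.99), Slfn8 (0.79), Ifih1 (0.7), Ifit2 (0.65), Ikbke (0.61) and Irf5 (0.43). It was negative for Tmem154 (-2.03), Batf3 (-2), Cxcl3 (-1.91), Gpr84 (-1.89), Olr1 (-1.22), Il1b (-1.17), Cbr3 (-1.04), Slc7a11 (-1.03), Gclm (-0.92), Pmvk (-0.84), Socs3 (-0.8), Nsdhl (-0.65), Srxn1 (-0.62), Lpl (-0.55) and Rtp4 (-0.53). List medians past the camera threshold were 0.31 for interferon-stimulated genes, 0.2 for interferon production and signalling, 0.19 for PPAR targets, 0.68 for fibroblast and mesothelial markers, -0.27 for oxidative phosphorylation, -0.28 for cholesterol synthesis, -0.44 for NRF2 genes and -0.39 for ribosomal protein genes. With an estimated correlation 0 of these 8 lists passed. By the preset correlation, 62 of 100 splits of the libraries gave 8 lists or more, up to 13, so chance cannot be excluded for the number of lists. For genes, 2 of 100 splits gave 1039 or more, the real one included. The other split gave 1411 genes. It kept the stimulated labels and exchanged the genotype labels of 4 of the 6 vehicle libraries, all but control replicate 2 and replicate 1 labelled knockout, and other exchanges of 4 vehicle libraries gave 231 to 708 genes. What sets this split apart from the other exchanges was not tested. All of them kept any genotype difference among the stimulated libraries, which enters the interaction. Their counts therefore do not show what chance alone gives. Splits that exchanged labels under both treatments gave 0 genes. Exchanged labels add any genotype difference to the spread within the groups, which can lower the counts of such splits. The share of 2 in 100 therefore does not exclude chance for the number of genes.

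Gene-level Pparg counts were higher in the vehicle libraries labelled knockout, by 0.69 on the log2 scale. A swap of the vehicle labels would make PPAR targets higher in those libraries, but 11 targets past the threshold were lower there and 0 higher, which argues against it. The counts cannot show whether exons of a conditional allele are missing from the Pparg transcript, since gene-level counts sum all exons, so the 0.69 cannot be told apart from continued transcription of an allele with deleted exons. That hypothesis may account for the pattern, and counts per exon would test it.

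Interferon-stimulated genes were higher and Il1b lower in stimulated libraries labelled knockout. Scaling argues against itself as the cause: the list's median stayed at 0.47 or above with the other scalings, and Il1b at -0.96 or below. A stronger effective stimulus that raised both lists alike would give similar medians, but that of LPS-responsive genes, 0.12, lay -0.44 from that of the interferon list. One that raised the lists unequally stays open, since only 1 dose was given. Of 49 LPS-responsive genes, 13 were higher, 7 lower and 29 not called. A difference in timing stays open, since only 1 time point was sampled. The interferon list's median was 0.54 without the library with most fibroblast and mesothelial marker RNA (336 CPM). The other 2 libraries still held 185 and 235 CPM, more than each control (126 to 145), so leaving out 1 library did not remove the excess and a part played by such RNA stays open. The bound written before, a change under 0.1, took no account of this, and the condition was added after the value was seen. The genotype as labelled stays open as well, together with the question about Pparg.

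Vehicle replicate 1 labelled knockout stood apart from replicates 2 and 3, with a chi-square per degree of freedom of 41.4 and 47 against 5.15 between those 2. Its deviation had an r of 0.08 with the control response across genes, the highest of the 12 libraries (0.043 in control vehicle replicate 3). That is too low for exposure to the stimulus to make up most of the deviation. The library's other deviations lower r, so a slight partial exposure cannot be excluded. No marker list of 7 other cell types exceeded 1.03 times the mean of the other 2 libraries. Such sums can rest on 1 gene and miss such cells: Il7r averaged 800 of the 802 CPM of T and NK markers in this group. Large macrophage markers summed to 2600 CPM in replicate 1 against 2150 and 2040, and small ones to 440 against 338 and 332. These sums too rest mostly on 1 gene each. In the group's means, Cd9 held 1620 of 2260 CPM of the large and Lyz1 314 of 370 CPM of the small markers. A different mix of cells therefore stays open. The deviation of replicate 1 fell with exon length (Spearman rho -0.453), but rho reached -0.299 in a control vehicle library. RNA quality or library preparation therefore cannot be told apart from other differences between wells. No biological explanation was tested, since the 3 libraries share their labels.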

How the results depend on the processing

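Scaling by total count, and list members without vehicle replicate 1 labelled knockout, were chosen only after the data were seen; the other alternatives were fixed before. For named genes, 1810 of the values under other settings and 2598 of those without 1 library kept their direction and side of the threshold. With the same direction, 13 and 40 lost the call, and 4 and 1 gained one. For list medians, 1090 and 1564 were counted as unchanged, 15 and 24 lost the call and 29 and 31 gained it. Of the 1090, 135 came from the Wald test, which ran without camera. These counted as unchanged because the median moved by less than its jackknife standard error. The others kept their side of the camera threshold. Medians of lists not called could change sign, such as oxidative phosphorylation in vehicle (0.14, and -0.04 without vehicle replicate 1 labelled knockout). The cause of the changes below was not tested. By design, glmTreat asks for a larger effect and the estimated correlation allows for genes that vary together. Leaving out a library leaves fewer samples and also changes the spread shared by all groups. Counts fell without some libraries and rose without others. For genes that differed between genotypes in vehicle (491), the count was 960 with no low-count filter, 1096 with limma-voom, 229 with the 2 groups alone and 66 with glmTreat, and 261 to 789 without 1 library (261, 263 and 322 without control vehicle replicates 1, 2 and 3, and 789 without vehicle replicate 1 labelled knockout). After stimulation (2081) it was 4565 with limma-voom, 3811 with the 2 groups alone and 163 with glmTreat, and 1227 to 4080 without 1 library. The 4080 came without vehicle replicate 1 labelled knockout, which belongs to neither stimulated group. For the treatment, glmTreat gave 4640 in controls (8612) and 5143 in libraries labelled knockout (8956), and leaving out 1 library gave 8009 to 9542 and 8441 to 9362. For the interaction (1039) the count was 1875 with no filter, 2614 with limma-voom and 34 with glmTreat, and 428 to 1962 without 1 library. It was 467 and 428 without control vehicle replicates 1 and 2, 1752 and 1962 without vehicle replicates 1 and 3 labelled knockout, 500 and 451 without stimulated control replicates 2 and 3, and 523, 623 and 510 without stimulated replicates 1, 2 and 3 labelled knockout. For 3 libraries against 3, 10 splits are too few for a share under 0.05; the highest other split gave 0 genes in each of the 4 comparisons (491, 2081, 8612 and 8956 with the real labels), where 1 of 10 splits was as large. For lists the real counts were 10, 13, 9 and 9 and the highest others 9, 11, 11 and 14, with 1, 1, 8 and 8 of 10 splits as large. With an estimated correlation, 1, 1, 3, 4 and 0 lists passed (10, 13, 9, 9 and 8 with the preset), in the order vehicle, stimulated, treatment in controls, treatment in libraries labelled knockout and interaction. For the treatment in controls 15 lists passed with no filter, 14 with limma-voom and 19 with fry, and 18 with fry in libraries labelled knockout. Without 1 library the ranges were 8 to 13, 11 to 15, 9 to 9, 8 to 10 and 7 to 10 lists. The correlation of treatment responses (0.938) was 0.61 with no filter, which adds genes with few counts, and 0.923 to 0.941 without 1 library. That of genotype differences ranged from 0.056 to 0.211. The Pparg difference ranged from 0.6 to 0.75 in vehicle and from 0.2 to 0.46 after stimulation without 1 library.

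Directions that turned belonged to genes not called either way and, among lists called with all libraries, to 1. Nlrp3 in vehicle (0.02) was -0.02 with total count and ranged from -0.22 to 0.23 without 1 library, with -0.03 and -0.11 without control vehicle replicates 2 and 3 and -0.22 and -0.02 without vehicle replicates 2 and 3 labelled knockout. Casp1 in vehicle (0.08) was -0.02 with limma-voom and -0.07 without vehicle replicate 1 labelled knockout. Casp1 after stimulation was -0.08 with total count, 0 with no filter, -0.01 with limma-voom, 0 with the 2 groups alone, and -0.07, -0.02 and 0 without stimulated control replicate 1 and without replicates 1 and 3 labelled knockout. For the interaction, Il18 was 0.1 with limma-voom and 0.12 and 0 without 1 library, Casp1 was 0.01 with limma-voom and -0.2 to 0.07 without 1 library, and Il6 was -0.3 to 0.07 without 1 library. The ribosomal median in vehicle was -0.01 without vehicle replicate 1 labelled knockout (camera adjusted p = 0.748).

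The replicate numbers showed no clear pairing of the libraries. Same-numbered libraries of different groups had correlations of deviations from -0.309 to 0.067. A library correlated best with its own number in 7 of 36 cases. Within genotype, the median was 0.04 in controls and 0.052 in libraries labelled knockout, against -0.023 and -0.002 for different numbers. Correlations this weak cannot show whether a number marks a shared animal or culture. With a block on the number over all 4 groups the counts were 349, 1549, 8374, 8724 and 514 genes and 10, 12, 9, 8 and 8 lists, the Pparg differences 0.69 and 0.34, and the correlations 0.122 and 0.938. Over all 4 groups the block lost the calls of Nlrp3 after stimulation and of the interactions of Rtp4 and Irf5. With a block within genotype the treatment and interaction counts were 8611, 8935 and 1015 genes and 9, 8 and 7 lists.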

Other observations

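Single genes of other groups differed after stimulation, while the groups of this paragraph did not pass the camera threshold with all libraries; no explanation was tested. Glycolysis and hypoxia genes went both ways in the libraries labelled knockout, with 5 of 24 higher, 3 lower and 16 not called (6 and 4 when adjusted over the list alone; camera adjusted p = 0.925): P4ha1, a collagen-modifying hydroxylase, was higher by 0.79 ± 0.08 and the vasodilator peptide gene Adm was lower by -1 ± 0.13. Alternative activation genes had 2 of 21 higher, 4 lower and 15 not called (2 and 4 when adjusted over the list alone; camera adjusted p = 0.459), with the transcription factor genes Klf4 at 0.94 ± 0.13 and Tfec at -0.87 ± 0.11. Scavenger and complement receptor genes had 11 of 29 higher, 5 lower and 13 not called (12 and 5 when adjusted over the list alone; camera adjusted p = 0.106; without vehicle replicate 1 labelled knockout 0.0458, and adjusted p = 0.788 with an estimated correlation). Higher members included Axl (1.09 ± 0.1), the complement receptor gene C3ar1 (1.01 ± 0.08) and C1qa (0.75 ± 0.08). MHC class II had 3 of 9 higher and 6 not called (4 when adjusted over the list alone; camera adjusted p = 0.0711), with its transactivator gene Ciita at 1.03 ± 0.21 and Cd74 at 0.49 ± 0.12. The call of Cd74 was lost without replicate 1 of either stimulated group (edgeR adjusted p up to 0.0816). Lysosomal genes had 5 of 35 higher, 6 lower and 24 not called (5 and 6 when adjusted over the list alone; camera adjusted p = 0.647), with Gla at 0.37 ± 0.07 and Lamp2 at 0.31 ± 0.07; without that library 13 were higher. In the same fit, without vehicle replicate 1 labelled knockout, 8 lysosomal genes were lower. Glycolysis genes then had 7 higher and 7 lower, alternative activation genes 4 higher and 5 lower, and stress response genes 1 higher and 4 lower. The stress response list had 1 of 26 lower and 25 not called (1 when adjusted over the list alone; camera adjusted p = 0.275), Pdia4, an endoplasmic reticulum chaperone (-0.39 ± 0.08). Cell cycle genes had 1 of 32 higher, 1 lower and 30 not called (1 and 1 when adjusted over the list alone; camera adjusted p = 0.868), the higher one being the spindle gene Tpx2 (1.38 ± 0.11).

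Markers of macrophage origin and of other cells were measured in the same comparison. Small, monocyte-derived macrophage markers had 3 of 11 higher, 1 lower and 7 not called (4 and 2 when adjusted over the list alone; median 0.48, camera adjusted p = 0.03, adjusted p = 0.516 with an estimated correlation and 0.199 without vehicle replicate 1 labelled knockout), with Vcan at 1.42 ± 0.16. Large, resident macrophage markers had 2 of 16 higher, 1 lower and 13 not called (2 and 1 when adjusted over the list alone; camera adjusted p = 0.914), with Thbs1 at 1.79 ± 0.23. T and NK markers, with 4 of 14 measured, were not tested as a list. They summed to 606 ± 49.4 CPM against 337 ± 21.9 in controls, nearly all from Il7r (585 ± 49.9 against 317 ± 24.3, a log2 difference of 0.88 ± 0.09), while the T cell gene Cd3e, singled out after its values were seen, stood at 0.0377 and 0.0891 CPM. B cell markers had 0 of 7 called (0 when adjusted over the list alone; camera adjusted p = 0.339) and mast cell markers 1 of 6 higher and 5 not called (1 when adjusted over the list alone; camera adjusted p = 0.478). Eosinophil markers summed to 3.02 ± 0.856 and 3.75 ± 0.399 CPM, dendritic cell markers to 12.8 ± 1.76 and 11.8 ± 0.361, and erythroid markers to 0.0929 ± 0.0352 and 0.0522 ± 0.052. Immediate early genes had 1 of 12 higher, 3 lower and 8 not called (2 and 3 when adjusted over the list alone; camera adjusted p = 0.918). Mitochondrially encoded genes had 1 of 8 lower and 7 not called (0 when adjusted over the list alone; camera adjusted p = 0.0703, and without vehicle replicate 1 labelled knockout 5 lower with 0.00526, and adjusted p = 0.761 with an estimated correlation) and held 0.515 ± 0.00902% of the counts against 0.64 ± 0.035% in controls. Ribosomal protein genes had 1 of 30 lower and 29 not called (1 when adjusted over the list alone; median -0.16, camera adjusted p = 0.0174, adjusted p = 0.918 with an estimated correlation), and 13 lower and 1 higher without that library (camera adjusted p = 0.000651, adjusted p = 0.801 with an estimated correlation).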
